A study of Mus musculus with 12 samples.

How the data were processed

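RNA was sequenced from the livers of 12 C57BL/6 mice, 3 in each of 4 groups: WT or hepatocyte Shp knockout, on chow or HFCF. Total RNA was extracted with Trizol and a column kit and made into stranded libraries after removal of ribosomal RNA, per the labels' protocols. The deposited table gives whole-number read counts per Ensembl gene and library, per the file headers. It also gives FPKM values, which the authors derived, per the file headers; each equaled its count divided by gene length and by a library total. The build was mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release were not given in the sources used here. No gene in the table had a highest count below 10. The FPKM values were not used in a test.

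Libraries held 13967116 to 18324134 counts over 15846 genes. Within each group, library pairs differed by more than sampling noise, with a chi-square per degree of freedom of 12.67 to 40.82 over genes with at least 20 counts, so none was treated as a repeat. Groups, replicate numbers and the assignment of columns came from the labels. The tests, the 45 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named below as chosen later. The lists held 1025 symbols, of which 917 were in the table.

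Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14736 and removed 1110. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with 4 group means and no other covariate. The common biological coefficient of variation was 0.119. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, per contrast. The contrasts were HFCF against chow in WT and in KO, KO against WT on chow and on HFCF, and their interaction. Lists with at least 5 tested members, 43 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera compares a list with all other tested genes. Ratios of genes with 1 to 3 counts in a group carry 95% counting intervals, and groups at 0 were set to a floor of 3 counts over the group. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

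Nr0b2 was named throughout. Per contrast the rule also named the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and groups that did not overlap. Provisional symbols and immunoglobulin or T cell receptor segments were left out of that part, and non-overlap was not asked of the interaction. From each list it named up to 4 members with the lowest adjusted p. The printed examples and lists were chosen from these after their values were seen, and some genes and lists whose calls rested on 1 library were passed over. Some genes that the rule named are not reported here.

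The pipeline was tested on simulated counts with 100 genes changed by a log2 of 1 and 100 by 2 among 14537 genes. For the diet contrast in KO, 85% and 97% were recovered, for the genotype contrast on HFCF 86% and 97%, and for the interaction 63% and 90%. Unchanged genes made up 8 of 190 calls, 13 of 196 (6.63%) and 8 of 161 in these contrasts, and 2 genes were called for the diet in WT, where none was changed. In a further simulation of the genotype contrast on HFCF over 14528 genes, a raised list of 25 genes was called, and 0 of 42 unchanged lists were called by camera. Genes were simulated as independent, so this could not test whether the preset correlation is high enough for real lists.

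Alternatives were RLE and upper quartile scaling, no filter, a stricter filter, the replicate number as a covariate, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma voom, a fit of the compared groups alone and leaving out each library. For lists they were camera with an estimated correlation and fry. A pseudocount alternative did not apply to counts. Leaving out each library for the correlations between contrasts was chosen after seeing the data.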

Results

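Gene expression was measured by RNA sequencing in the livers of 12 C57BL/6 mice aged 5 months. The mice formed 4 groups of 3: wild type (WT) or hepatocyte knockout (KO) of Shp, each fed chow or the diet that the labels call HFCF. Shp, gene symbol Nr0b2, encodes an orphan nuclear receptor without a DNA-binding domain that acts as a transcriptional corepressor. The deposited table held counts for 15846 genes. Total counts were 13967116, 14397297 and 14672866 in the WT chow livers, and 17772906, 14480571 and 15094978 in the KO chow livers. They were 17371095, 14429864 and 15032229 in the WT HFCF livers, and 14329648, 14443656 and 18324134 in the KO HFCF livers. A filter on low counts left 14736 genes for testing. The first principal component held 46.4% of the variance and separated the genotypes, and the second held 17.4% and separated the diets. In what follows, ± after a log2 fold change is its standard error from edgeR's quasi-likelihood fit of all 12 libraries, ± after CPM (counts relative to library size, scaled with TMM factors) is the SD over 3 livers, and adjusted p is the Benjamini-Hochberg value over all tested genes or lists.

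Nr0b2 (ENSMUSG00000037583, mm10 chromosome 4, 133553376 to 133556536, plus strand, protein coding) was measured first, since it is the targeted gene. It stood at 49.3, 22.4 and 31 CPM in WT chow livers and at 0.775, 0.552 and 1.01 CPM in KO chow livers. On HFCF it stood at 47.6, 49.6 and 53.4 CPM in WT and at 0.509, 0.21 and 0.394 CPM in KO. All 6 KO libraries lay below all 6 WT libraries. The log2 fold change between genotypes was -5.44 ± 0.32 on chow (edgeR adjusted p = 1.7e-07) and -7.05 ± 0.35 on HFCF (edgeR adjusted p = 3.37e-08). The diet effect on Nr0b2 did not pass the test in WT (0.55 ± 0.20, edgeR adjusted p = 0.0875) or in KO (-1.06 ± 0.63, edgeR adjusted p = 0.409), nor did the interaction (-1.61 ± 0.66, edgeR adjusted p = 0.305). The diet effect in WT passed without WT chow replicate 1 (edgeR adjusted p = 0.00274) and with limma voom (adjusted p = 0.0436). It also passed with the replicate number as a covariate (edgeR adjusted p = 0.0369).

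**Figure D1:**
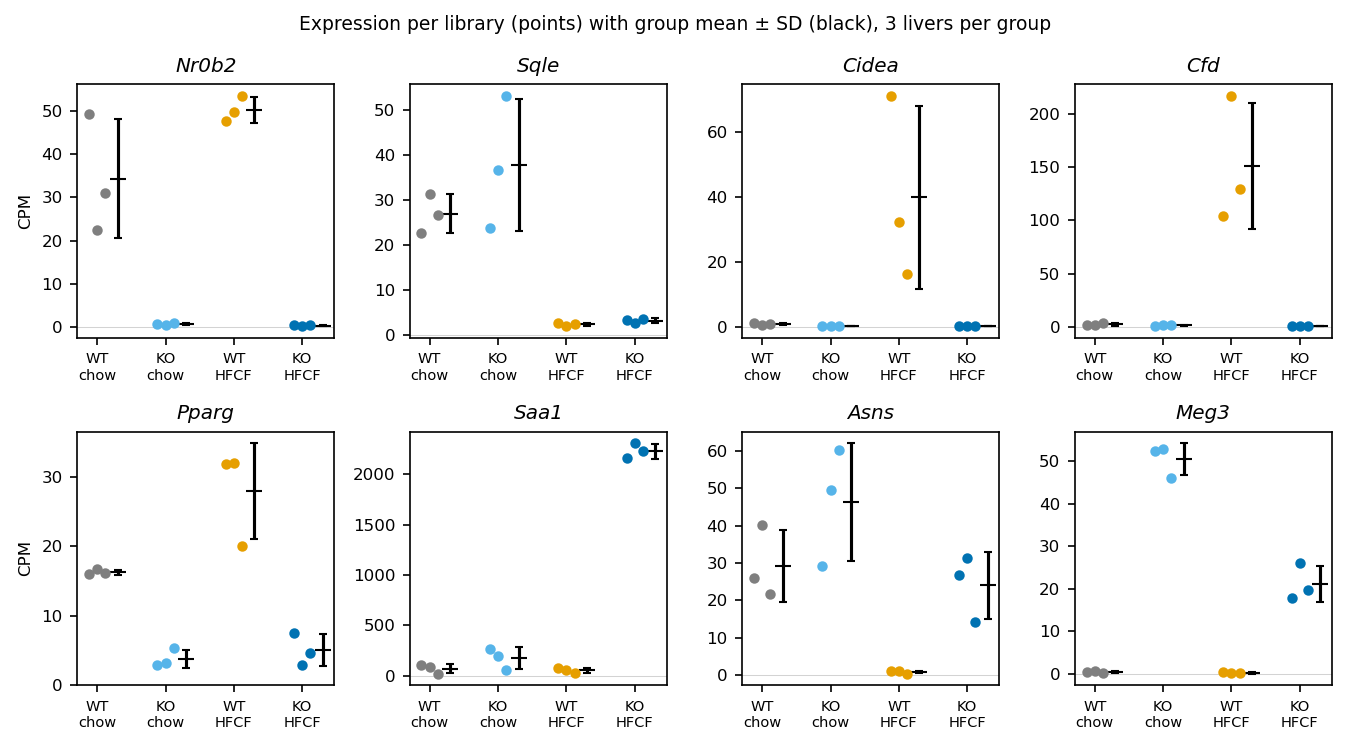
CPM (y axis, linear, from 0) of 8 genes in each of the 12 libraries (colored points), by group (x axis), with the mean and SD of 3 livers in black. Nr0b2 is near 0 in every KO liver, Cfd and Cidea are high in WT HFCF livers, Saa1 is high in KO HFCF livers, Sqle is low in both HFCF groups and Meg3 is near 0 in every WT liver.

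The first comparison asked what the HFCF diet changed in WT livers. Camera called the lipogenesis and lipid droplet lists up and the cholesterol synthesis list down. With an estimated correlation the first 2 were not called (adjusted p = 0.393 and 0.238), and cholesterol synthesis was (0.026). Cfd, which encodes the adipose-derived complement factor D (chromosome 10, 79890853 to 79892656), rose from 2.36 ± 1.38 to 151 ± 59.1 CPM, a log2 fold change of 5.98 ± 0.34 (edgeR adjusted p = 4.25e-07). Cidea, a lipid droplet protein (chromosome 18, 67343564 to 67367794), rose from 0.963 ± 0.296 to 39.8 ± 28.2 CPM (5.36 ± 0.51, edgeR adjusted p = 3e-05). Of the WT HFCF livers replicate 1 stood apart, with a chi-square per degree of freedom of 38.1 and 40.82 against replicates 2 and 3, which gave 12.67 against each other. Its second principal component was -38, against -23.9 and -16.1. Cidea stood at 71, 32.2 and 16.2 CPM in these 3 livers. Sqle, which encodes the cholesterol synthesis enzyme squalene epoxidase, fell from 26.9 ± 4.35 to 2.29 ± 0.365 CPM (-3.54 ± 0.28, edgeR adjusted p = 7.8e-06). In all, 2013 genes changed (edgeR adjusted p under 0.05), 1144 up and 869 down, of which 288 rose and 119 fell by at least 2-fold. The other large rises were Cyp2b9 at 5.14 ± 1.17, Themis at 3.84 ± 0.36, Ntrk2 at 3.74 ± 0.43 and Gpnmb at 3.70 ± 0.72. The other large falls were Asns, the asparagine synthetase gene, at -5.03 ± 0.46, Cyp2b10 at -3.38 ± 0.37, Nipal1 at -2.94 ± 0.92, Enho at -2.92 ± 0.27 and the chemokine gene Cxcl13 at -2.81 ± 0.44. The call of Nipal1 (edgeR adjusted p = 0.0498) ended without WT chow replicate 1, 2 or 3 (0.0643, 0.165 and 0.0839) and without WT HFCF replicate 2 or 3 (0.133 and 0.109). It also ended with RLE scaling (0.0507), no filter (0.0503), DESeq2 (adjusted p = 0.102) and limma voom (0.168), and limma voom did not call Cyp2b9 (0.158) or Gpnmb (0.0549).

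Among the lipid lists, cholesterol synthesis and SREBP2 targets fell in WT on HFCF, as 18 fell and 6 were not called of 24 tested members (1 up and 20 down adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -0.95 and camera gave an adjusted p = 4.31e-33, or adjusted p = 0.026 with an estimated correlation. Examples are Cyp51 at -2.57 ± 0.14 and Hsd17b7 at -1.60 ± 0.12, which encode enzymes of the sterol pathway. In de novo lipogenesis and triglyceride synthesis, 10 rose, 3 fell and 15 were not called of 28 tested members (12 up and 3 down adjusted over the list alone). Lipogenesis genes had a median log2 fold change of 0.32 and camera gave an adjusted p = 3.39e-05, or adjusted p = 0.393 with an estimated correlation. Srebf1, the transcription factor of fatty acid synthesis, rose by 2.27, Scd1, the stearoyl-CoA desaturase, by 2.50 and Thrsp by 3.35 on the log2 scale. In the lipid droplet and fatty acid uptake list, 14 rose, 2 fell and 10 were not called of 26 tested members (18 up and 2 down adjusted over the list alone). Lipid droplet genes had a median log2 fold change of 0.50 and camera gave an adjusted p = 5.86e-12, or adjusted p = 0.238 with an estimated correlation. Lpl (lipoprotein lipase) rose by 1.58 and Cd36 (fatty acid uptake) by 1.47. Of adipose markers, 4 rose and 2 were not called of 6 tested members (4 up adjusted over the list alone). Adipose markers had a median log2 fold change of 0.92 and camera gave an adjusted p = 3.74e-07, or adjusted p = 0.026 with an estimated correlation. Of bile acid and sterol transport genes, 5 rose, 1 fell and 9 were not called of 15 tested members (6 up and 1 down adjusted over the list alone), with the sterol exporters Abcg5 at 1.38 ± 0.10 and Abcg8 at 1.02 ± 0.11. Sterol transport genes had a median log2 fold change of 0.19 and camera gave an adjusted p = 0.000892, or adjusted p = 0.0488 with an estimated correlation. The calls of these lists that held with an estimated correlation in this comparison were cholesterol synthesis, adipose markers, bile acid and sterol transport, and one-carbon metabolism.

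Camera also called the matrix, interferon, macrophage and proliferation lists up in WT on HFCF, with under 50% of the members called up in each, and none of these calls held with an estimated correlation. Of fibrosis and extracellular matrix genes, 19 rose, 2 fell and 18 were not called of 39 tested members (22 up and 2 down adjusted over the list alone), with the collagen genes Col3a1 at 2.24 ± 0.35, Col1a2 at 1.66 ± 0.28 and Col6a2 at 1.26 ± 0.21. Matrix genes had a median log2 fold change of 0.60 and camera gave an adjusted p = 6.91e-09, or adjusted p = 0.31 with an estimated correlation. In the interferon response list, 15 rose and 20 were not called of 35 tested members (20 up and 1 down adjusted over the list alone), with Oasl2 at 1.25 ± 0.19 and Ifi44 at 1.88 ± 0.30. Interferon genes had a median log2 fold change of 0.77 and camera gave an adjusted p = 4.01e-10, or adjusted p = 0.393 with an estimated correlation. Of lipid-associated macrophage markers, 8 rose, 1 fell and 8 were not called of 17 tested members (11 up and 2 down adjusted over the list alone). Lipid-associated macrophage markers had a median log2 fold change of 0.88 and camera gave an adjusted p = 2.98e-06, or adjusted p = 0.379 with an estimated correlation. For macrophage and monocyte markers, 7 rose and 24 were not called of 31 tested members (12 up adjusted over the list alone), with the chemokine receptor gene Cx3cr1 at 2.07 ± 0.42. Macrophage markers had a median log2 fold change of 0.51 and camera gave an adjusted p = 1.89e-05, or adjusted p = 0.604 with an estimated correlation. The camera call of that list ended without WT HFCF replicate 1 (adjusted p = 0.0921) and with fry (0.162). Of proliferation genes, 6 rose and 16 were not called of 22 tested members (14 up and 1 down adjusted over the list alone), with Mki67 at 1.41 ± 0.27. Proliferation genes had a median log2 fold change of 0.73 and camera gave an adjusted p = 3.62e-05, or adjusted p = 0.393 with an estimated correlation. Of B and plasma cell markers, 0 rose, 0 fell and 18 were not called of 18 tested members (0 adjusted over the list alone). B and plasma cell markers had a median log2 fold change of -0.02, 0.02 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 0.531, or adjusted p = 0.909 with an estimated correlation. By edgeR 0 of them rose and 3 fell at an unadjusted p under 0.05, and DESeq2 called 0 up and 0 down. For endothelial cell markers, 1 rose and 22 were not called of 23 tested members (0 adjusted over the list alone). Endothelial markers had a median log2 fold change of 0.10 and camera gave an adjusted p = 0.429, or adjusted p = 0.909 with an estimated correlation.

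Camera called the ER stress, one-carbon and hepatocyte lists down in WT on HFCF, with under 50% of the members called down in each. In the ER stress and unfolded protein response list, 1 rose, 12 fell and 17 were not called of 30 tested members (1 up and 17 down adjusted over the list alone), with the chaperone gene Dnajb11 at -0.51 ± 0.10. ER stress genes had a median log2 fold change of -0.27 and camera gave an adjusted p = 3.74e-07, or adjusted p = 0.335 with an estimated correlation. Atf5, a transcription factor gene of that list, fell by 1.00 ± 0.12 on the log2 scale. In one-carbon and sulfur amino acid metabolism, 3 rose, 10 fell and 15 were not called of 28 tested members (3 up and 11 down adjusted over the list alone), with Csad (taurine synthesis) at -1.42 ± 0.14, Nnmt (nicotinamide methylation) at -1.96 ± 0.25 and Mat1a (S-adenosylmethionine synthesis) at -0.97 ± 0.13. One-carbon genes had a median log2 fold change of -0.13 and camera gave an adjusted p = 0.000109, or adjusted p = 0.0488 with an estimated correlation. Of hepatocyte markers, 6 fell and 14 were not called of 20 tested members (7 down adjusted over the list alone). Hepatocyte markers had a median log2 fold change of -0.22 and camera gave an adjusted p = 0.0011, or adjusted p = 0.31 with an estimated correlation. Leaving out 1 library moved the count of changed genes by over 1.5 times in 3 fits, to 1255 without WT chow replicate 1, 1100 without WT chow replicate 3 and 1303 without WT HFCF replicate 1. The values of the 2 groups did not overlap in 31.1% of tested genes, against 10% by chance.

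The second comparison asked what the diet changed in KO livers. Camera called the cholesterol synthesis list down here too, and the acute phase list up. The first call held with an estimated correlation (adjusted p = 0.00141) and the second did not (0.174). Saa1, an acute phase apolipoprotein gene (chromosome 7, 46740501 to 46742980), rose from 174 ± 107 to 2230 ± 71.8 CPM (3.69 ± 0.61, edgeR adjusted p = 0.00572), and Saa2 from 76.8 ± 45.8 to 2000 ± 112 CPM (4.70 ± 0.60, edgeR adjusted p = 0.000956). Saa1 and Saa2 are near-identical neighbors, so their separate values are uncertain. Sqle fell from 37.8 ± 14.7 to 3.13 ± 0.493 CPM (-3.58 ± 0.27, edgeR adjusted p = 7.35e-06). In all, 390 genes changed (edgeR adjusted p under 0.05), 216 up and 174 down, of which 62 rose and 66 fell by at least 2-fold. Among genes that the rule named, the largest rise was that of Moxd1, a monooxygenase gene, at 5.82 ± 0.40. It was followed by Saa2, Saa1, Lcn2 (lipocalin 2) at 2.97 ± 0.51, Chi3l1 at 2.52 ± 0.59 and Orm2 (orosomucoid) at 2.51 ± 0.38. Large falls were those of Idi1 (isoprenoid synthesis) at -3.97 ± 0.37, Sqle, Ugt2b37 at -3.15 ± 0.33, Cyp51 at -2.63 ± 0.14 and Cxcl13 at -2.50 ± 0.38. The call of Chi3l1 (edgeR adjusted p = 0.0391) ended without KO chow replicate 1 or 2 (0.174 and 0.104) and without KO HFCF replicate 1, 2 or 3 (0.127, 0.11 and 0.0576).

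In cholesterol synthesis and SREBP2 targets in KO, 18 fell and 6 were not called of 24 tested members (22 down adjusted over the list alone), with Fdps (farnesyl diphosphate synthesis) at -2.47 ± 0.23. Cholesterol synthesis genes had a median log2 fold change of -0.98 and camera gave an adjusted p = 7.89e-78, or adjusted p = 0.00141 with an estimated correlation. Of acute phase genes, 11 rose and 15 were not called of 26 tested members (18 up adjusted over the list alone), with Saa3 at 1.38 ± 0.22 and Hpx, the hemopexin gene, at 0.86 ± 0.14. Acute phase genes had a median log2 fold change of 0.85 and camera gave an adjusted p = 1.25e-19, or adjusted p = 0.174 with an estimated correlation. In the interferon response list, 3 rose and 32 were not called of 35 tested members (22 up adjusted over the list alone). Interferon genes had a median log2 fold change of 0.64 and camera gave an adjusted p = 3.72e-13, or adjusted p = 0.525 with an estimated correlation. Ifit2 is 1 of those that rose, at 1.13 ± 0.21 (edgeR adjusted p = 0.0122), a call that ended without KO chow replicate 1 (0.0705) or KO HFCF replicate 1 (0.0559). Of Kupffer cell markers, 2 rose and 13 were not called of 15 tested members (5 up adjusted over the list alone), with the folate receptor gene Folr2 at 0.98 ± 0.17. Kupffer markers had a median log2 fold change of 0.27 and camera gave an adjusted p = 0.00384, or adjusted p = 0.525 with an estimated correlation. Of B and plasma cell markers, 4 fell and 14 were not called of 18 tested members (7 down adjusted over the list alone), with the immunoglobulin genes Ighg1 at -1.88 ± 0.14 and Igkc at -1.06 ± 0.11, and Igj (J chain) at -0.79 ± 0.11. B and plasma cell markers had a median log2 fold change of -0.72 and camera gave an adjusted p = 1.87e-13, or adjusted p = 0.0195 with an estimated correlation. Fry did not call the interferon (adjusted p = 0.143) and Kupffer cell lists (0.121). In the KO diet comparison, the camera calls that held with an estimated correlation were those of cholesterol synthesis and of B and plasma cells.

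Camera called the xenobiotic and NRF2 lists down with the diet in KO, with most members of each not called. Fry did not call these lists (adjusted p = 0.0885 and 0.143), nor did camera with an estimated correlation. In the xenobiotic metabolism list, 6 fell and 22 were not called of 28 tested members (2 up and 6 down adjusted over the list alone). Xenobiotic genes had a median log2 fold change of -0.12, -0.20 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 0.00147, or adjusted p = 0.401 with an estimated correlation. Its members Cyp2c29 and Cyp3a11, both cytochrome P450 genes, stood at -0.93 ± 0.12 and -1.43 ± 0.19. Cyp2b10 had 66 counts in KO chow and 3 in KO HFCF, a ratio of 20.8 with a counting interval of 6.82 to 104. Such intervals, and the floor of 3 counts used below where a group had 0, cover counting error only. In the NRF2 and oxidative stress list, 6 fell and 21 were not called of 27 tested members (9 down adjusted over the list alone), with the glutathione transferase genes Gsta2 at -1.43 ± 0.24, Gsta4 at -0.65 ± 0.12 and Gstm6 at -0.79 ± 0.16. NRF2 list members had a median log2 fold change of -0.19 and camera gave an adjusted p = 0.000349, or adjusted p = 0.53 with an estimated correlation. The call of Gsta4 ended without KO chow replicate 1 (edgeR adjusted p = 0.0537) and without KO HFCF replicate 1 or 2 (0.0728 and 0.0531). That of Gstm6 ended without KO chow replicate 1 (0.0856) and KO HFCF replicate 2 (0.0821), and paralogs make the counts of Gsta and Gstm genes uncertain. De novo lipogenesis was not called as a list, and 1 rose, 2 fell and 25 were not called of 28 tested members (4 up and 7 down adjusted over the list alone), with Srebf1 at 1.07 ± 0.16. Lipogenesis genes had a median log2 fold change of -0.03 and a mean of 0.01 while the test pointed down, and camera gave an adjusted p = 0.665, or adjusted p = 0.927 with an estimated correlation. Its test pointed the other way without KO chow replicate 3 (adjusted p = 0.962) and KO HFCF replicate 2 (0.799). In the lipid droplet list, 3 rose and 23 were not called of 26 tested members (6 up and 2 down adjusted over the list alone), with Lpl at 1.09 ± 0.12. Lipid droplet genes had a median log2 fold change of 0.00 and a mean of 0.13 while the test pointed up, and camera gave an adjusted p = 0.0189, or adjusted p = 0.727 with an estimated correlation. Its camera call ended without KO chow replicate 2 or 3 (adjusted p = 0.0839 and 0.0681) and without KO HFCF replicate 1 or 3 (0.0934 and 0.166), with limma voom (0.158) and with fry (0.405). The sterol exporters Abcg5 and Abcg8 rose by 1.31 and 0.99 on the log2 scale. Of fibrosis genes, 0 rose, 0 fell and 39 were not called of 39 tested members (0 adjusted over the list alone). Matrix genes had a median log2 fold change of 0.04 and a mean of 0.02 while the test pointed down, and camera gave an adjusted p = 0.882, or adjusted p = 0.965 with an estimated correlation. By edgeR 2 of them rose and 4 fell at an unadjusted p under 0.05, and DESeq2 called 0 up and 1 down. The direction of that list turned without KO HFCF replicate 2 (camera adjusted p = 0.21) and with a surrogate variable (0.959). Of hepatocyte markers, 1 rose and 19 were not called of 20 tested members (4 up and 1 down adjusted over the list alone). Hepatocyte markers had a median log2 fold change of 0.09 and camera gave an adjusted p = 0.221, or adjusted p = 0.727 with an estimated correlation. The count of 390 became 157 without KO chow replicate 1, 254 without KO chow replicate 2, 169 without KO HFCF replicate 1 and 178 without KO HFCF replicate 2. DESeq2 called 656 genes, an added surrogate variable gave 891, and a fit of the compared groups alone gave 603. The values did not overlap in 24.4% of tested genes, against 10% by chance.

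**Figure D2:**
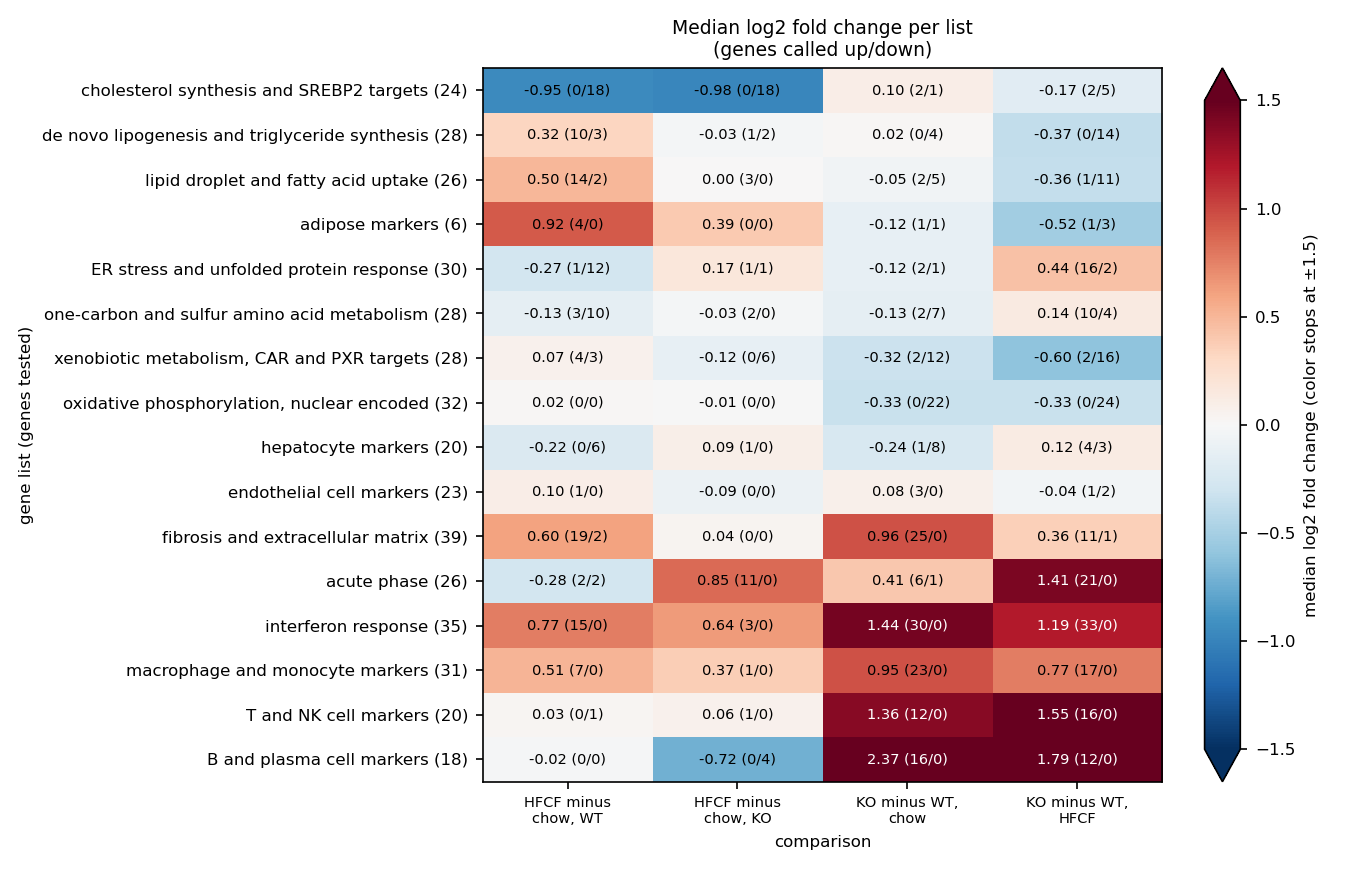
Median log2 fold change (color, and number in each cell) of 16 gene lists (y axis, with the number of tested genes) in 4 comparisons (x axis), with the numbers of genes called up and down by edgeR in brackets. Cholesterol synthesis is lower on HFCF in both genotypes (-0.95 and -0.98), and B and plasma cell markers are higher in KO on both diets (2.37 and 1.79).

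The third comparison asked how KO livers differed from WT livers on chow. In every comparison of KO with WT, a cohort difference between the mice could not be told apart from the deletion. Camera called the B and plasma cell, interferon, macrophage and matrix lists up in KO, and the oxidative phosphorylation and xenobiotic lists down. B and plasma cells were also called with an estimated correlation (adjusted p = 2.72e-05), and the others were not (0.156, 0.239, 0.153, 0.275 and 0.196). Igkc, the constant region of the immunoglobulin kappa chain (chromosome 6, 70726435 to 70726757), rose from 1.55 ± 0.207 to 289 ± 38 CPM (7.54 ± 0.17, edgeR adjusted p = 4.26e-12). Meg3, a maternally expressed noncoding RNA of the Dlk1-Dio3 imprinted region (chromosome 12, 109541001 to 109571726), rose from 0.447 ± 0.229 to 50.5 ± 3.76 CPM (6.80 ± 0.24, edgeR adjusted p = 5.97e-10). Pparg, a nuclear receptor of fat storage, fell from 16.3 ± 0.35 to 3.78 ± 1.32 CPM (-2.11 ± 0.29, edgeR adjusted p = 0.000405). In all, 2289 genes changed (edgeR adjusted p under 0.05), 1432 up and 857 down, of which 617 rose and 95 fell by at least 2-fold. Of the largest rises outside immunoglobulin segments, Rian, Meg3, Rtl1 and Mirg lie in that imprinted region. Rian stood at 7.96 ± 0.31 and Mirg at 5.97 ± 0.51. Rtl1 had 302 counts in KO and 3 in WT, a ratio of 88.5 with a counting interval of 30 to 432. Gldn (gliomedin) stood at 5.77 ± 0.56 and Gpnmb, a glycoprotein of lipid-laden macrophages, at 5.26 ± 0.65. Other large falls were those of Olig1 at -3.73 ± 0.30, the major urinary protein gene Mup17 at -3.64 ± 0.67, Slc22a26 at -3.25 ± 0.56 and Rcan2 at -3.07 ± 0.24. Mup17 and Slc22a26 have close paralogs, so their counts are uncertain, as are those of Rtl1, since a transcript of the opposite strand is known to overlap it and the strand setting of the counting was not given in the sources used here.

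Camera called 5 of the immune lists given here and the matrix list up in KO on chow, but with an estimated correlation the B and plasma cell list alone of these. The others then had an adjusted p = 0.156 for interferon, 0.169 for cytokines, 0.239 for macrophages, 0.196 for T and NK cells and 0.153 for matrix. Of B and plasma cell markers, 16 rose and 2 were not called of 18 tested members (17 up adjusted over the list alone), with Ighg1 at 10.92 ± 0.26, Ighg2c at 9.99 ± 0.50 and Igj at 6.42 ± 0.17. B and plasma cell markers had a median log2 fold change of 2.37 and camera gave an adjusted p = 1.85e-85, or adjusted p = 2.72e-05 with an estimated correlation. This was the list whose camera call held with an estimated correlation in the chow comparison. In the interferon response, 30 rose and 5 were not called of 35 tested members (33 up adjusted over the list alone), with the regulator Irf7 at 1.98 ± 0.16, Usp18 at 2.78 ± 0.24 and Ifi44 at 2.92 ± 0.27. Interferon genes had a median log2 fold change of 1.44 and camera gave an adjusted p = 1.78e-31, or adjusted p = 0.156 with an estimated correlation. Of inflammatory cytokines and chemokines, 16 rose, 1 fell and 9 were not called of 26 tested members (19 up and 1 down adjusted over the list alone), with Ccl2, a monocyte attractant, at 3.15 ± 0.50 and Il1rn at 1.72 ± 0.26. Cytokine genes had a median log2 fold change of 1.13, 1.17 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 1.45e-09, or adjusted p = 0.169 with an estimated correlation. Ccl22 had 31 counts in KO and 1 in WT, a ratio of 27.3 with a counting interval of 4.54 to 1110. Of macrophage and monocyte markers, 23 rose and 8 were not called of 31 tested members (27 up adjusted over the list alone), with the monocyte marker Ly6c2 at 3.66 ± 0.48 and the elastase gene Mmp12 at 3.14 ± 0.45. Macrophage markers had a median log2 fold change of 0.95 and camera gave an adjusted p = 1.31e-17, or adjusted p = 0.239 with an estimated correlation. Of T and NK cell markers, 12 rose and 8 were not called of 20 tested members (16 up adjusted over the list alone), with Cd5 at 2.64 ± 0.48. T and NK cell markers had a median log2 fold change of 1.36, 1.44 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 2.09e-07, or adjusted p = 0.196 with an estimated correlation. Pdcd1, the PD-1 gene, had 58 counts in KO and 1 in WT, a ratio of 51 with a counting interval of 8.8 to 2050. In the fibrosis and extracellular matrix list, 25 rose and 14 were not called of 39 tested members (32 up adjusted over the list alone), with Col6a3 at 1.60 ± 0.18, Col6a2 at 1.67 ± 0.20 and the gelatinase gene Mmp2 at 1.49 ± 0.19. Matrix genes had a median log2 fold change of 0.96 and camera gave an adjusted p = 4.15e-18, or adjusted p = 0.153 with an estimated correlation. Endothelial markers were not called as a list, and 3 rose and 20 were not called of 23 tested members (2 up adjusted over the list alone). Endothelial markers had a median log2 fold change of 0.08 and camera gave an adjusted p = 0.104, or adjusted p = 0.687 with an estimated correlation. With limma voom that list was called (camera adjusted p = 0.0347).

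Camera called the oxidative phosphorylation, hepatocyte and xenobiotic lists down in KO on chow, but not with an estimated correlation (adjusted p = 0.275, 0.196 and 0.196). In nuclear-encoded oxidative phosphorylation, 22 fell and 10 were not called of 32 tested members (28 down adjusted over the list alone), with the succinate dehydrogenase gene Sdha at -0.38 ± 0.07. Oxidative phosphorylation genes had a median log2 fold change of -0.33 and camera gave an adjusted p = 6.7e-12, or adjusted p = 0.275 with an estimated correlation. Of hepatocyte markers, 1 rose, 8 fell and 11 were not called of 20 tested members (1 up and 12 down adjusted over the list alone), with Hpd (tyrosine breakdown) at -0.81 ± 0.11 and the arginase gene Arg1 at -0.67 ± 0.11. Hepatocyte markers had a median log2 fold change of -0.24 and camera gave an adjusted p = 0.000136, or adjusted p = 0.196 with an estimated correlation. In xenobiotic metabolism, 2 rose, 12 fell and 14 were not called of 28 tested members (3 up and 13 down adjusted over the list alone), with Cyp2c29 at -1.22 ± 0.12 and Cyp2b10 at -2.44 ± 0.34. Xenobiotic genes had a median log2 fold change of -0.32 and camera gave an adjusted p = 0.000169, or adjusted p = 0.196 with an estimated correlation. De novo lipogenesis was not called as a list, and 4 fell and 24 were not called of 28 tested members (5 down adjusted over the list alone), with Dgat1 (triglyceride synthesis) at -0.45 ± 0.10. Lipogenesis genes had a median log2 fold change of 0.02 and a mean of -0.06 while the test pointed down, and camera gave an adjusted p = 0.359, or adjusted p = 0.806 with an estimated correlation. Nor was the lipid droplet list, of which 2 rose, 5 fell and 19 were not called of 26 tested members (4 up and 7 down adjusted over the list alone). Lipid droplet genes had a median log2 fold change of -0.05 and camera gave an adjusted p = 0.0505, or adjusted p = 0.697 with an estimated correlation. Its members Plin4 (a droplet coat protein) at -2.68 ± 0.31, Fitm1 at -1.99 ± 0.19 and Cd36 at -1.21 ± 0.17 fell, while Lpl rose at 1.72 ± 0.13. The lipid droplet list was called without WT chow replicate 1 (camera adjusted p = 0.0187) or KO chow replicate 1 (0.0362), with a surrogate variable (0.00869), with no filter (0.0394) and in a fit of the compared groups alone (0.000108). Of nuclear receptors and SHP partners, 1 rose, 2 fell and 19 were not called of 22 tested members (1 up and 2 down adjusted over the list alone). Nuclear receptor genes had a median log2 fold change of 0.01 and a mean of -0.03 while the test pointed down, and camera gave an adjusted p = 0.32, or adjusted p = 0.697 with an estimated correlation. The count of 2289 became 1152 without WT chow replicate 3 and 1442 without KO chow replicate 2. The values did not overlap in 36.1% of tested genes, against 10% by chance.

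The fourth comparison asked how KO livers differed from WT livers on HFCF. Camera called the lipogenesis and lipid droplet lists down in KO against WT, and the acute phase, interferon and B and plasma cell lists up. B and plasma cells held with an estimated correlation (adjusted p = 0.00023), and the others did not (0.214, 0.204, 0.144 and 0.155). Cidea stood at 39.8 ± 28.2 CPM in WT and 0.242 ± 0.043 CPM in KO (-7.33 ± 0.62, edgeR adjusted p = 4.72e-06). Cfd stood at 151 ± 59.1 CPM in WT and 0.719 ± 0.267 CPM in KO (-7.65 ± 0.39, edgeR adjusted p = 4.46e-08). Pparg fell from 28 ± 6.93 to 5.01 ± 2.3 CPM (-2.49 ± 0.27, edgeR adjusted p = 4.48e-05), and Saa2 rose from 29 ± 18.5 to 2000 ± 112 CPM (6.11 ± 0.65, edgeR adjusted p = 3.43e-05). In all, 2814 genes changed (edgeR adjusted p under 0.05), 1558 up and 1256 down, of which 570 rose and 214 fell by at least 2-fold. The rankings here follow the naming rule, which left out immunoglobulin segments and provisional symbols. Under it the largest rises were Moxd1 at 10.20 ± 0.60, Gldn and Rian at 6.91 ± 0.30. Next were Mirg, Meg3 at 6.35 ± 0.27 and Saa2. Gldn had 269 counts in KO and 0 in WT, at least 92.9-fold higher against a floor of 3 counts over the group. Mirg had 260 counts in KO and 2 in WT, a ratio of 135 with a counting interval of 36.9 to 1120. The largest falls besides Cfd, Cidea and Nr0b2 were Slc22a27, H2-Q2 and Mogat1. Slc22a27 had 176 counts in WT and 1 in KO, a ratio of 170 with a counting interval of 30.1 to 6750. H2-Q2, a class I histocompatibility gene (ENSMUSG00000079507, 1 of 2 genes with this symbol), stood at -5.18 ± 0.55 and Mogat1 (monoacylglycerol acyltransferase) at -4.43 ± 0.52. H2-Q2 and Slc22a27 belong to families of close paralogs, so their counts are uncertain.

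Camera called the lipogenesis, lipid droplet and adipose lists down in KO on HFCF, but not with an estimated correlation (adjusted p = 0.214, 0.204 and 0.144). The cholesterol synthesis list was not called (camera adjusted p = 0.0896). In de novo lipogenesis and triglyceride synthesis, 14 fell and 14 were not called of 28 tested members (1 up and 14 down adjusted over the list alone), with Srebf1 at -1.10 ± 0.15, Scd1 at -1.73 ± 0.29 and Thrsp at -2.36 ± 0.40. Lipogenesis genes had a median log2 fold change of -0.37 and camera gave an adjusted p = 8.52e-07, or adjusted p = 0.214 with an estimated correlation. In the lipid droplet and fatty acid uptake list, 1 rose, 11 fell and 14 were not called of 26 tested members (2 up and 12 down adjusted over the list alone), with Plin4 at -3.79 ± 0.33, Cd36 at -2.15 ± 0.17 and Fitm1 at -2.09 ± 0.18, while Lpl rose at 1.23 ± 0.12. Lipid droplet genes had a median log2 fold change of -0.36 and camera gave an adjusted p = 7.4e-09, or adjusted p = 0.204 with an estimated correlation. Of adipose markers, 1 rose, 3 fell and 2 were not called of 6 tested members (1 up and 3 down adjusted over the list alone). Adipose markers had a median log2 fold change of -0.52 and camera gave an adjusted p = 0.00103, or adjusted p = 0.144 with an estimated correlation. In xenobiotic metabolism, 2 rose, 16 fell and 10 were not called of 28 tested members (3 up and 18 down adjusted over the list alone), with Cyp2c29 at -2.39 ± 0.13 and Gstt1 at -1.55 ± 0.13. Xenobiotic genes had a median log2 fold change of -0.60, -0.65 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 8.36e-09, or adjusted p = 0.0939 with an estimated correlation. Gsta2, a glutathione transferase gene, stood at -2.76 ± 0.22. Of pericentral zonation genes, 1 rose, 9 fell and 10 were not called of 20 tested members (3 up and 10 down adjusted over the list alone), with Glul (glutamine synthetase) at -1.02 ± 0.12 and Cyp2a5 at -2.15 ± 0.25. Pericentral genes had a median log2 fold change of -0.40 and camera gave an adjusted p = 0.000378, or adjusted p = 0.181 with an estimated correlation. In oxidative phosphorylation, 24 fell and 8 were not called of 32 tested members (29 down adjusted over the list alone), with Sdha at -0.50 ± 0.07 and Sdhb at -0.44 ± 0.08. Oxidative phosphorylation genes had a median log2 fold change of -0.33 and camera gave an adjusted p = 1.08e-10, or adjusted p = 0.261 with an estimated correlation. Of nuclear receptors and SHP partners, 6 fell and 16 were not called of 22 tested members (6 down adjusted over the list alone), with Nr1i3, the receptor CAR, at -0.77 ± 0.16. Nuclear receptor genes had a median log2 fold change of -0.12 and camera gave an adjusted p = 0.0115, or adjusted p = 0.214 with an estimated correlation. Cyp2c29, Gsta2 and Cyp2a5 have close paralogs, and their counts are uncertain.

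Camera called the acute phase, complement, interferon, B and plasma cell, and T and NK cell lists up in KO on HFCF. With an estimated correlation it called the B and plasma cell list alone of these (acute phase 0.144, complement 0.214, interferon 0.155, and T and NK cells 0.144, as adjusted p). In the acute phase list, 21 rose and 5 were not called of 26 tested members (21 up adjusted over the list alone), with Saa3 at 2.99 ± 0.25, Orm1 at 1.91 ± 0.17 and Hpx at 1.40 ± 0.14. Acute phase genes had a median log2 fold change of 1.41 and camera gave an adjusted p = 1.22e-20, or adjusted p = 0.144 with an estimated correlation. In complement and coagulation, 15 rose, 1 fell and 13 were not called of 29 tested members (17 up and 1 down adjusted over the list alone), with C3 at 1.48 ± 0.14. Complement genes had a median log2 fold change of 0.37 and camera gave an adjusted p = 2.27e-06, or adjusted p = 0.214 with an estimated correlation. In the interferon response, 33 rose and 2 were not called of 35 tested members (34 up adjusted over the list alone), with Irf7 at 1.66 ± 0.15 and Usp18 at 2.18 ± 0.22. Interferon genes had a median log2 fold change of 1.19 and camera gave an adjusted p = 5.64e-24, or adjusted p = 0.155 with an estimated correlation. Of B and plasma cell markers, 12 rose and 6 were not called of 18 tested members (14 up adjusted over the list alone), with Igkc at 6.89 ± 0.17. B and plasma cell markers had a median log2 fold change of 1.79, 1.74 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 1.29e-50, or adjusted p = 0.00023 with an estimated correlation. Ighg1 had 5756 counts in KO and 1 in WT, a ratio of 5960 with a counting interval of 1070 to 236000. This was the list whose camera call held with an estimated correlation in the HFCF comparison. Of T and NK cell markers, 16 rose and 4 were not called of 20 tested members (19 up adjusted over the list alone), with Thy1 at 2.46 ± 0.34. T and NK cell markers had a median log2 fold change of 1.55, 1.48 with groups of at most 3 counts at the floor, and camera gave an adjusted p = 2.47e-09, or adjusted p = 0.144 with an estimated correlation. Pdcd1 had 45 counts in KO and 1 in WT, a ratio of 46.6 with a counting interval of 7.95 to 1880.

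Further lists on HFCF covered macrophages, matrix and protein folding. Of macrophage and monocyte markers, 17 rose and 14 were not called of 31 tested members (23 up adjusted over the list alone), with Ly6c2 at 3.24 ± 0.40 and Mpeg1 at 1.50 ± 0.20. Macrophage markers had a median log2 fold change of 0.77 and camera gave an adjusted p = 1.66e-10, or adjusted p = 0.268 with an estimated correlation. Of Kupffer cell markers, 9 rose and 6 were not called of 15 tested members (9 up and 1 down adjusted over the list alone), with Cd163 at 1.37 ± 0.16 and Clec4f at 0.67 ± 0.12. Kupffer markers had a median log2 fold change of 0.75 and camera gave an adjusted p = 0.000105, or adjusted p = 0.18 with an estimated correlation. In the fibrosis list, 11 rose, 1 fell and 27 were not called of 39 tested members (12 up and 1 down adjusted over the list alone). Matrix genes had a median log2 fold change of 0.36 and camera gave an adjusted p = 0.00571, or adjusted p = 0.482 with an estimated correlation. Its camera call ended without WT HFCF replicate 3 (adjusted p = 0.0976). In the ER stress and unfolded protein response list, 16 rose, 2 fell and 12 were not called of 30 tested members (17 up and 3 down adjusted over the list alone), with Asns at 4.74 ± 0.47, Sdf2l1 at 1.54 ± 0.25 and the chaperone gene Calr at 0.80 ± 0.14. ER stress genes had a median log2 fold change of 0.44 and camera gave an adjusted p = 1.31e-05, or adjusted p = 0.261 with an estimated correlation. Of hepatocyte markers, 4 rose, 3 fell and 13 were not called of 20 tested members (5 up and 5 down adjusted over the list alone), among them Trf (transferrin) at 0.65 ± 0.09 and Ttr (transthyretin) at -0.57 ± 0.10. Hepatocyte markers had a median log2 fold change of 0.12 and camera gave an adjusted p = 0.799, or adjusted p = 0.881 with an estimated correlation. For endothelial markers, 1 rose, 2 fell and 20 were not called of 23 tested members (1 up and 1 down adjusted over the list alone). Endothelial markers had a median log2 fold change of -0.04 and camera gave an adjusted p = 0.482, or adjusted p = 0.742 with an estimated correlation. The direction of the hepatocyte list turned without WT HFCF replicate 1 (camera adjusted p = 0.847), and that of the endothelial list without WT HFCF replicate 3 (0.962). The values did not overlap in 34.2% of tested genes, against 10% by chance.

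The fifth comparison asked which diet effects differed between the genotypes, as the difference between the diet effect in KO and that in WT. Camera gave the acute phase list a higher and the lipogenesis list a lower diet effect in KO, but not with an estimated correlation (adjusted p = 0.144 and 0.254). Of 117 genes with an interaction (edgeR adjusted p under 0.05), 55 had a higher and 62 a lower diet effect in KO. The largest values that follow are those among genes that the rule named. The largest positive values were Saa1 at 4.09 ± 0.82 (edgeR adjusted p = 0.0423), Asns at 4.08 ± 0.58 (0.0136), Saa2 at 4.03 ± 0.78 (0.0401), Enho at 2.95 ± 0.34 (0.0034), Fgl1 at 2.87 ± 0.57 (0.0409) and Nnmt at 1.97 ± 0.35 (0.0341). The largest negative values were Cfd at -6.88 ± 0.75 (0.0034), Gpnmb at -4.99 ± 0.84 (0.0341), Gpr98 at -2.87 ± 0.55 (0.0377), Ugt2b37 at -2.76 ± 0.51 (0.0341), Thrsp at -2.75 ± 0.59 (0.0497) and Aacs at -2.68 ± 0.58 (0.0497). The interactions of Cidea (-6.05 ± 1.47, edgeR adjusted p = 0.0751) and Cd36 (-0.94 ± 0.24, 0.0826) did not pass the test. DESeq2 called both (adjusted p = 2.78e-11 and 0.00556), as did the fit with a surrogate variable (0.000272 and 0.015), and Cidea passed without WT HFCF replicate 1 (0.0173) or 3 (0.014). Both also passed with the replicate number as a covariate (edgeR adjusted p = 0.0103 and 0.044), which ended other interaction calls given below. Leaving out WT chow replicate 1, 2 or 3 gave 16, 32 and 32 genes, and leaving out KO chow replicate 1 or 3 gave 18 and 17. Leaving out WT HFCF replicate 2 gave 46, and leaving out KO HFCF replicate 1, 2 or 3 gave 23, 11 and 20. DESeq2 called 344 and a surrogate variable gave 282. Of 24 called interaction genes named here, 4 (Asns, Enho, Cfd and Cyp2c29) stayed called in all 12 fits without 1 library, and all 24 kept their sign. The highest adjusted p of the others in such a fit was 0.124. Limma voom did not call Saa1 (adjusted p = 0.0515), Asns (0.0625), Gpnmb (0.079), Gpr98 (0.101), Ugt2b37 (0.0766), Thrsp (0.093), Aacs (0.0691) or Col6a2 (0.0632), and with no filter Aacs was not called (0.0501). Without WT chow replicate 1, 2 or 3, 5, 5 and 10 of the 24 stayed called, and without KO chow replicate 1, 2 or 3, 5, 19 and 5. Without WT HFCF replicate 1, 2 or 3 the numbers were 19, 8 and 20, and without KO HFCF replicate 1, 2 or 3 they were 5, 5 and 4.

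In the acute phase list, 8 had a higher diet effect in KO and 18 were not called of 26 tested members (14 higher adjusted over the list alone), with Itih3 at 1.51 ± 0.27, Hpx at 1.02 ± 0.19 and Hp (haptoglobin) at 1.23 ± 0.24. Acute phase genes had a median log2 fold change of 1.07 and camera gave an adjusted p = 4.93e-21, or adjusted p = 0.144 with an estimated correlation. In the ER stress and unfolded protein response list, 5 had a higher diet effect in KO and 25 were not called of 30 tested members (15 higher adjusted over the list alone), with Calr at 1.10 ± 0.20 and Hsp90b1 at 0.90 ± 0.18. ER stress genes had a median log2 fold change of 0.33 and camera gave an adjusted p = 9.72e-14, or adjusted p = 0.144 with an estimated correlation. In one-carbon and sulfur amino acid metabolism, 3 had a higher diet effect in KO and 25 were not called of 28 tested members (10 higher and 2 lower adjusted over the list alone), with Mat1a at 1.00 ± 0.18 and Csad at 0.91 ± 0.19. One-carbon genes had a median log2 fold change of 0.28 and camera gave an adjusted p = 1e-06, or adjusted p = 0.0388 with an estimated correlation. In de novo lipogenesis, 3 had a lower diet effect in KO and 25 were not called of 28 tested members (7 lower adjusted over the list alone), with Srebf1 at -1.20 ± 0.22. Lipogenesis genes had a median log2 fold change of -0.30 and camera gave an adjusted p = 3.84e-07, or adjusted p = 0.254 with an estimated correlation. In the lipid droplet list, 1 had a lower diet effect in KO and 25 were not called of 26 tested members (3 lower adjusted over the list alone), with Cidec at -2.62 ± 0.51. Lipid droplet genes had a median log2 fold change of -0.40 and camera gave an adjusted p = 2.09e-07, or adjusted p = 0.254 with an estimated correlation. Of adipose markers, 1 had a lower diet effect in KO and 5 were not called of 6 tested members (2 lower adjusted over the list alone). Adipose markers had a median log2 fold change of -0.45 and camera gave an adjusted p = 6.45e-07, or adjusted p = 0.0388 with an estimated correlation. In the fibrosis list, 1 had a lower diet effect in KO and 38 were not called of 39 tested members (17 lower adjusted over the list alone), with Col6a2 at -1.30 ± 0.28. Matrix genes had a median log2 fold change of -0.55 and camera gave an adjusted p = 2.95e-12, or adjusted p = 0.196 with an estimated correlation. Of lipid-associated macrophage markers, 1 had a higher diet effect in KO, 1 had a lower diet effect in KO and 15 were not called of 17 tested members (1 higher and 8 lower adjusted over the list alone). Lipid-associated macrophage markers had a median log2 fold change of -0.49 and camera gave an adjusted p = 1.28e-05, or adjusted p = 0.332 with an estimated correlation. Of hepatocyte markers, 1 had a higher diet effect in KO and 19 were not called of 20 tested members (8 higher adjusted over the list alone). Hepatocyte markers had a median log2 fold change of 0.36 and camera gave an adjusted p = 1.07e-06, or adjusted p = 0.144 with an estimated correlation. The detoxification genes Cyp2c29 and Gsta3 stood at -1.16 ± 0.17 and -0.61 ± 0.12. Of the 24 lists called by camera, those of adipose markers and one-carbon metabolism held with an estimated correlation. Fry called 4, and did not call acute phase (adjusted p = 0.0605), lipogenesis (0.116), lipid droplets (0.116), fibrosis (0.0744) or lipid-associated macrophages (0.144).

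**Figure D3:**
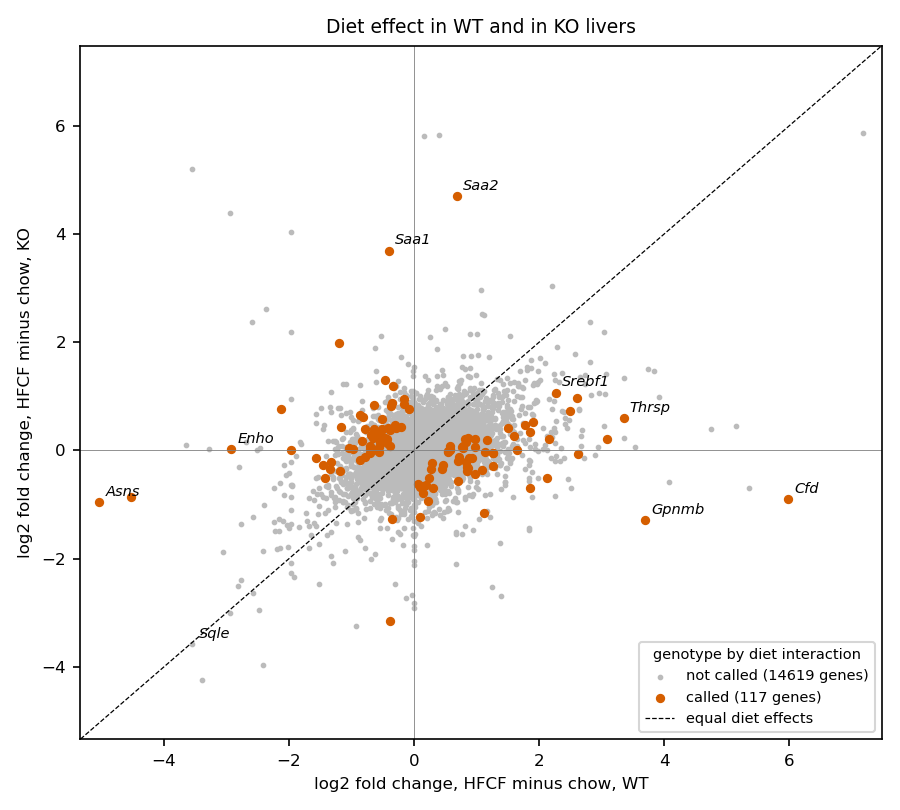
Log2 fold change of HFCF against chow in WT (x axis) and in KO (y axis) for 14736 tested genes, each point a gene, with the 117 genes of the interaction in orange and a dashed line where both are equal. Saa1 and Saa2 lie far above the line, Asns and Enho above it on the left, and Cfd, Gpnmb and Thrsp below it.

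Across all tested genes, the diet effects in WT and KO had a Pearson r of 0.38 and a Spearman rho of 0.39. These 2 comparisons share no libraries, and genes are not independent replicates. Of genes called in each, 114 rose in both, against 16.8 for independent lists, 80 fell in both, against 10.3, and 2 went opposite ways. Of the 2013 genes called in WT, 82.1% had the same sign in KO, where their median log2 change in that direction was 0.20, against 0.55 in WT. Choosing genes by their call in WT inflates the WT median, so these medians do not compare the sizes of the diet effects. The genotype effects on chow and on HFCF had an r of 0.78 and a rho of 0.55. Here 784 genes rose in both, against 151.4 for independent lists, 429 fell in both, against 73.0, and 11 went opposite ways. Of genes called on chow, 91.3% had the same sign on HFCF.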

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

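The results here were singled out because the diet effect differed between the genotypes by a test of the interaction; the count over other splits was planned, and the fits without 1 library for the named genes were too. Groups of 3 livers were too small to test for outlying libraries by the rule used here, though WT HFCF replicate 1 stood apart from its group.

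The interaction was called for 117 genes by edgeR (adjusted p under 0.05) and for 24 lists by camera. With an estimated correlation 2 of these lists were called, adipose markers and one-carbon metabolism, and fry called 4. The diet effect was higher in KO than in WT for the acute phase genes Saa1 (4.09), Saa2 (4.03), Itih3 (1.51), Hpx (1.02) and Hp (1.23), and for Fgl1 (2.87), all as log2 differences. It was also higher for Asns (4.08), Enho (2.95), Nnmt (1.97), Mat1a (1.00), Csad (0.91), Calr (1.10) and Hsp90b1 (0.90). Of these, Asns, Enho, Nnmt, Mat1a and Csad fell with the diet in WT, so their higher values do not by themselves mean a rise in KO. The diet effect was lower in KO for Cfd (-6.88), Gpnmb (-4.99), Gpr98 (-2.87), Ugt2b37 (-2.76), Thrsp (-2.75), Aacs (-2.68) and Cidec (-2.62). Srebf1 (-1.20), Col6a2 (-1.30), Cyp2c29 (-1.16) and Gsta3 (-0.61) were lower too. Gpnmb and Col6a2 were already higher in KO than in WT on chow, so their lower diet effects do not by themselves mean low levels in KO. Of these 24 genes, 4 stayed called in every fit without 1 library, and limma voom did not call 8, Asns among them.

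Among the lists, most of which were not called with an estimated correlation, the median interaction was 1.07 for acute phase, 0.33 for ER stress, 0.28 for one-carbon metabolism and 0.36 for hepatocyte markers. It was -0.45 for adipose markers, -0.40 for lipid droplets, -0.30 for lipogenesis, -0.55 for fibrosis and -0.49 for lipid-associated macrophages.

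Regrouping the libraries gave a count to set beside each result. For the interaction, 6 of 100 drawn splits, the real one included, called at least 117 genes, and the highest other called 4359. The 5 others called 4359, 698, 437, 178 and 140 genes, and each held unequal numbers of true WT livers under the WT label on the 2 diets. The genotype effect, a structure of the samples, thereby enters their interaction, so this count neither measures nor excludes chance. Divided in this way after the counts were seen, the 48 other splits with equal numbers called at most 1 gene, but they mix the genotypes within groups, which widens the spread, so they do not exclude chance either. The 10 splits of 3 livers against 3 are too few for a share under 0.05. The real split had the most genes for the diet in WT (2013, highest other 1) and KO (390, 1), and the genotype on chow (2289, 0) and HFCF (2814, 0). The others mix true groups too, so they do not measure chance.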

How the results depend on the processing

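All alternatives were planned except leaving out each library for the correlations between contrasts, which was chosen after seeing the data. RLE and upper quartile scaling, both filters and limma voom kept the gene counts within 1.5 times, and no scaling moved the share of rises by over 10 points. DESeq2 called 656 genes for the diet in KO and 344 for the interaction, a surrogate variable gave 891 and 282, and a fit of the compared groups alone gave 603 for the diet in KO. With an estimated correlation 4 lists were called for the diet in WT, 2 for the diet in KO, 1 for the genotype on chow, 1 on HFCF and 2 for the interaction, and fry called 4 for the diet in KO and 4 for the interaction. Leaving out each library gave 1100 to 2264 genes for the diet in WT, 157 to 336 in KO, 1152 to 1691 for the genotype on chow and 11 to 136 for the interaction, and 10 to 18 lists for the diet in KO. Without WT HFCF replicate 1, which stood apart from its group, the counts were 1303 genes for the diet in WT, 2631 for the genotype on HFCF and 92 for the interaction. Fewer libraries per fit are part of that construction, and otherwise the cause was not tested. Across genes the diet effects in WT and KO had an r of 0.32 to 0.37 without 1 library, and the genotype effects 0.74 to 0.79, or 0.71 over genes of at least 10 CPM. Cyp7a1 on chow, which was not called, turned to -0.01 with RLE scaling and with DESeq2, 0.00 with no filter, -0.03 with a surrogate variable, -0.27 without WT chow replicate 1 and -0.20 without KO chow replicate 1, with a range of -0.27 to 0.27. No other named gene turned direction under an alternative, and 26 of 185 values of named genes, each a gene in 1 comparison, lost their call in some fit without 1 library. These values leave out some genes whose calls rested on 1 library, so they understate such losses among all genes that the rule named.

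List directions turned in these cases, and the cause was not tested. The fibrosis list in KO turned with a surrogate variable (camera adjusted p = 0.959) and without KO HFCF replicate 2 (0.21, range 0.21 to 0.96), and bile acid synthesis in WT with limma voom (0.972). Lipogenesis in KO turned without KO chow replicate 3 (camera adjusted p = 0.962) and KO HFCF replicate 2 (0.799), with a range of 0.353 to 0.962. On HFCF the hepatocyte list turned without WT HFCF replicate 1 (camera adjusted p = 0.847, range 0.368 to 0.962) and the endothelial list without WT HFCF replicate 3 (0.962, range 0.204 to 0.962). None of these lists was called in the fit of all libraries. Depth limits genes with at most 3 counts in a group, whose ratios span wide counting intervals.

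The labels state no pairing of livers by replicate number. Of 18 same-numbered pairs, 4 had a correlation of deviations over 0.1 (-0.15 to 0.17). Between WT chow and WT HFCF the same-numbered pairs had 0.08, 0.17 and 0.11, and between KO chow and KO HFCF -0.04, -0.05 and -0.15. For 7 of 12 libraries the mean correlation with libraries of the same number in other groups was above that with the differently numbered ones. A link between livers of the same number was thus neither shown nor excluded. With a replicate block the counts were 1813, 386, 2113, 2673 and 97 genes and 18, 13, 21, 27 and 25 lists, in the order of the report's comparisons. No count moved by over 1.5 times, and 75 of the 117 interaction genes were shared. Of the 185 values of named genes 6 lost and 3 gained a call with the block, and of 70 values of lists 1 lost and 1 gained it. Lost were Nipal1 for the diet in WT and the interactions of Thrsp, Aacs, Hsp90b1, Col6a2 and Csad (edgeR adjusted p from 0.0539 to 0.068). Gained were Nr0b2 for the diet in WT and the interactions of Cidea and Cd36. On chow the bile acid synthesis list lost its call (camera adjusted p = 0.0575) and the lipid droplet list gained one (0.0137).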

Other observations

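Tests chosen only after the result was seen were all tests of the immunoglobulin pattern, the chow part of the hepatocyte share test, the stellate cell and cohort tests of the Dlk1-Dio3 pattern, the counts and values of genes near Nr0b2, and the values of Cyp7a1 and Cyp8b1 by genotype. The ratios at the floor, the wider set of immunoglobulin segments and the removal of provisional segments from the chromosome 12 test were also set after first results were seen. The test of B cells of every stage had a bound of 3, which the fitted gap passed and the median gap at the floor missed, and it was then changed to sums per library, which passed it. Ranges in brackets after medians and gaps below are 95% bootstrap intervals over genes, which carry no spread between livers. The gap per library has a Welch 95% interval over livers instead.

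Camera called the circadian list up with the diet in WT, but not with an estimated correlation (adjusted p = 0.4). In that list, 7 rose, 3 fell and 11 were not called of 21 tested members (12 up and 4 down adjusted over the list alone), with Arntl at -2.14 ± 0.28, Clock at -0.62 ± 0.10 and Per3 at 1.09 ± 0.18. Clock genes had a median log2 fold change of 0.40 and camera gave an adjusted p = 0.00123, or adjusted p = 0.4 with an estimated correlation. Members went both ways, so the direction of the list does not describe them all. A difference between the diet groups other than the diet, such as the time of collection, was not tested. It could not be told apart from the diet. Of bile acid synthesis genes, 2 rose, 3 fell and 12 were not called of 17 tested members (5 up and 5 down adjusted over the list alone). Bile acid synthesis genes had a median log2 fold change of 0.08 and a mean of -0.08 while the test pointed down, and camera gave an adjusted p = 0.858, or adjusted p = 0.933 with an estimated correlation. Cyp8b1, the sterol 12-alpha hydroxylase of cholic acid synthesis, fell by 1.00 ± 0.18 on the log2 scale. The direction of that list turned with limma voom (camera adjusted p = 0.972).

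Of bile acid synthesis genes by genotype on chow, 3 fell and 14 were not called of 17 tested members (2 up and 3 down adjusted over the list alone). Bile acid synthesis genes had a median log2 fold change of -0.16 and camera gave an adjusted p = 0.0402, or adjusted p = 0.207 with an estimated correlation. Cyp27a1 stood at -0.55 ± 0.09. The camera call ended without WT chow replicate 2 (adjusted p = 0.0577) or KO chow replicate 2 (0.0901), with the stricter filter (0.0582), with a surrogate variable (0.0612), in a fit of the compared groups alone (0.0883) and with an estimated correlation. Cyp7a1, the rate-limiting enzyme of the classic pathway, had log2 values of 0.01 on chow (edgeR adjusted p = 0.993) and 0.90 on HFCF (0.0546), and Cyp8b1 had -0.39 (0.169) and 0.61 (0.0323). The chow value of Cyp7a1 turned to -0.27 without WT chow replicate 1 and -0.20 without KO chow replicate 1. On HFCF the Cyp7a1 value passed without WT HFCF replicate 1 (1.28, edgeR adjusted p = 0.00927), with upper quartile scaling (0.0492), a surrogate variable (0.0408) and limma voom (0.0424). The Cyp8b1 call ended without WT HFCF replicate 2 or 3 (edgeR adjusted p = 0.133 and 0.102), without KO HFCF replicate 1 or 3 (0.14 and 0.0676) and in a fit of the compared groups alone (0.0799). Of male-biased liver genes on HFCF, 11 rose, 1 fell and 14 were not called of 26 tested members (11 up and 2 down adjusted over the list alone), with Cyp4a12b at 1.29 ± 0.12. Male-biased genes had a median log2 fold change of 0.62 and camera gave an adjusted p = 1.49e-05, or adjusted p = 0.325 with an estimated correlation.

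Immunoglobulin transcripts summed to 16.5 ± 1.19 CPM in WT chow, 1690 ± 249 in KO chow, 14.8 ± 2.81 in WT HFCF and 837 ± 59.3 in KO HFCF, and of 70 tested genes 60 rose on chow and 58 on HFCF. With 27 of them at 0 and 30 at 1 to 3 counts in WT chow, ratios were taken at the floor, where the chow median was 5.08 against a fitted 7.20. Segments elsewhere, at a median of 4.86 (4.08 to 6.18), argued against a strain haplotype on distal chromosome 12. A gap of 4.94 (4.35 to 5.50) over endothelial markers argued against a lower hepatocyte share alone. Lymphoid tissue or B cells of every stage as the whole source were argued against. Immunoglobulin sums rose 102-fold and B cell surface genes 2.81-fold on chow. The gap was 5.15 (4.62 to 5.67) per library and 3.56 (2.91 to 4.15) as a median at the floor. The genes were taken up for large rises, which favored wide gaps. A cohort difference cannot be told apart from genotype, as all 6 KO libraries lay above every WT library.

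Of 32 oxidative phosphorylation genes, 22 were called lower in KO on chow and 24 on HFCF, with medians of -0.33 and -0.33, a list not called with an estimated correlation. After a loess fit on gene length the HFCF median was -0.40 (-0.44 to -0.34), and on GC content -0.42 (-0.44 to -0.36), so neither removed it. On HFCF the hepatocyte list lay 0.45 above it (0.16 to 0.65), but its members went both ways. On chow the gap was 0.10 (-0.09 to 0.20). A lower hepatocyte share thus stayed open on both diets. The 9 tested mitochondrially encoded genes had medians of 0.34 on chow and 0.15 on HFCF. Camera did not call the list (adjusted p = 0.197 and 0.326). DESeq2 and edgeR called 3 up and 0 down on each diet. Whether these genes follow the hepatocyte share was not tested.

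The Dlk1-Dio3 transcripts Meg3, Rian, Mirg and Rtl1 summed to 0.836 CPM in WT chow and 126 in KO chow, and to 0.747 and 72 on HFCF. More stellate cells or fibroblasts as the whole source were argued against by a gap of 6.38 (5.81 to 7.69) over stellate markers. These 4 too were taken up for large rises. A haplotype of another strain could not be excluded or shown: 9 of 89 other genes of the region were called on both diets, against 1156 of 14569 elsewhere, an odds ratio of 1.31 (0.574 to 2.61, Fisher's exact p = 0.429). Before segments with provisional names were removed it was 3.04, with 22 of 106. A cohort difference may also be the source and cannot be told apart from genotype, as all 6 KO libraries lay above every WT library.

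Genes near Nr0b2 gave no excess that passed a test in 2 windows, but its nearest neighbors on 1 side were higher in KO. On chow and HFCF, Nudc had log2 values of 0.85 and 1.46 (edgeR adjusted p = 8.42e-05 and 4.45e-07), 1810019J16Rik 1.44 and 1.34 (0.000378 and 0.000352) and Gm17688 1.68 and 1.20 (0.000695 and 0.00344). Within 1 Mb, 6 of 43 were called on both diets, 14% against 8.3% elsewhere (odds ratio 1.79, Fisher's exact p = 0.167). Within 10 Mb, 25 of 268 were (odds ratio 1.14, Fisher's exact p = 0.503).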
